A study of Mus musculus with 16 samples.

How the data were processed

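Gene expression was measured by RNA sequencing in organoids grown from mouse endometrial epithelium, the cell layer that lines the uterus. Per the labels, the organoids came from control mice with floxed Tgfbr2 or from Tgfbr2 conditional knockout (cKO) mice that also carried the PR-Cre recombinase. The culture ran for 2 days before treatment. Vehicle was then given for 6 days, or 10 nM estradiol (E2) for 2 days and 10 nM E2 with 1 µM medroxyprogesterone acetate (MPA, a synthetic progestin) for 4 days. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and TruSeq RNA libraries were sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the mouse build GRCm39, without versions. The strand setting of the counting is not given in the sources used here.

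The authors deposited 1 table of 23306 genes in 16 libraries whose unit is a signal, gene read counts divided by a size factor per library. Multiplied by its factor, every value gave a whole number of reads within 0.01 read (100% of the values in every library). The factors matched the median-of-ratios factors of the recovered reads to a relative difference of 1.1e-15. Recovered depth was 14372111 to 20016836 reads per library. Each gene in the table has at least 17 reads over all libraries. Symbols came from GENCODE M21 names matched on Ensembl identifiers for 22484 genes, and the 822 others hold 1.84% of the reads. No coordinates are given, because the names come from an annotation of another build.

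The labels put the 16 libraries, M1 to M16, into 4 groups of 4 by genotype and treatment. They do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries of a group differed by as little as counting noise (smallest chi-square per degree of freedom 6.97, M10 and M11). Values were analysed as log2(value + 1), a scale that understates the change of genes with low values. The 16509 genes with a value of at least 10 in at least 4 libraries were tested and 6797 were left out. All 16 libraries entered 1 limma fit (version 3.58.1, R 4.3.3) with a mean per group and a mean-variance trend. It tested the hormone effect in each genotype, the genotype effect under each treatment and the interaction of both, each against a change in either direction, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values in the text come from this limma fit unless another tool is named. edgeR's quasi-likelihood test (version 4.0.16) on the recovered reads called 1497 genes for the hormone effect in control, 678 in cKO, 0 for genotype under vehicle, 1 under E2/MPA and 0 for the interaction.

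The fit was tested on simulated counts of 16509 genes with 50 genes changed at each fold. The changed genes had a mean of at least 50, and the genes of all folds were changed in the same run. At 1.5-fold, 2-fold, 4-fold and 8-fold it recovered 40%, 70%, 96% and 100% for the hormone effect in control and 32%, 74%, 92% and 100% in cKO. For the genotype effect it recovered 36%, 70%, 98% and 98% under vehicle and 34%, 66%, 86% and 98% under E2/MPA, and for the interaction 10%, 48%, 92% and 92%. These shares do not cover genes with lower means. They may be too high for a comparison in which few genes change, because the adjustment is then stricter. None of 29 lists was called in any simulated comparison. The changed genes were drawn without regard to the lists, so a list could hold some of them. The simulated genes varied independently, so this count says nothing about lists whose genes vary together. The 29 gene lists of pathways and cell types had 465 members, 438 of them in the table. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison.

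The genes named are Tgfbr2, Pgr and Esr1 in every comparison. Per comparison of a pair of groups they are also up to 10 genes with the largest rise and 10 with the largest fall among those with an adjusted p under 0.05, no overlap between the libraries of the groups, a mean of at least 50 in the higher group and a name that is not a predicted model. For the interaction they are up to 10 genes with an adjusted p under 0.05 and a mean of at least 50 in the highest group. For each list described they are up to 4 members past 0.05 with the lowest adjusted p or, where fewer than 2 passed, the 2 with the highest mean. Some genes that this rule names are not reported here. A gene outside this rule is said to have been chosen after its values were seen. The groups, tests, lists, naming rule and 15 alternative settings, besides leaving out each library in turn, were fixed before the data were examined. They covered the pseudocount, the filter, the scaling, edgeR and DESeq2 (version 1.42.0) on the recovered reads, the libraries in the fit, library weights, a robust fit, a fold threshold, camera with an estimated correlation and fry. A further 5 settings were chosen after seeing the data, 4 of them because stromal marker levels differed between libraries of a group and 1, a random block, because libraries 8 numbers apart deviated together.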

Results

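The data were 16 RNA-seq libraries of mouse endometrial epithelial organoids. There were 4 libraries each of control organoids under vehicle (M1 to M4), cKO organoids under vehicle (M5 to M8), control organoids under E2/MPA (M9 to M12) and cKO organoids under E2/MPA (M13 to M16). Recovered depth was 14599423 to 20016836 reads in the control vehicle libraries, 14377987 to 19458493 in cKO vehicle, 14381840 to 19290170 in control E2/MPA and 14372111 to 19102256 in cKO E2/MPA. Levels are normalized read counts, given as mean ± SD (n = 4), and fold changes are on the log2(value + 1) scale.

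Tgfbr2 (ENSMUSG00000032440), which encodes the type II TGF-beta receptor and is the target of the deletion, was read in every library. Under vehicle its level was 6014 ± 1467 in control and 4325 ± 811 in cKO organoids, and under E2/MPA it was 5356 ± 1685 in control and 4326 ± 850 in cKO. The cKO mean was thus 71.9% of control under vehicle and 80.8% under E2/MPA. Neither difference passed the test (log2 fold change -0.46, SE 0.21, adjusted p = 0.833 under vehicle; -0.28, SE 0.21, adjusted p = 0.690 under E2/MPA). Under vehicle the cKO libraries M5 to M7 (3520 to 4304) lay below the control libraries M1 to M3 (4852 to 6101), and under E2/MPA M13 to M15 (3568 to 4269) overlapped M9 to M11 (4103 to 5152). M4, M8, M12 and M16 had the highest stromal marker level of their groups and are called stroma-rich. The stroma-rich cKO libraries M8 (5439) and M16 (5526) lay above the control libraries M2 (5047) and M10 (4377). They lay below the stroma-rich control libraries M4 (8054) and M12 (7794). The values are totals over the gene and the labels do not say which exons are deleted, so this level does not check the genotype labels.

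**Figure D1:**
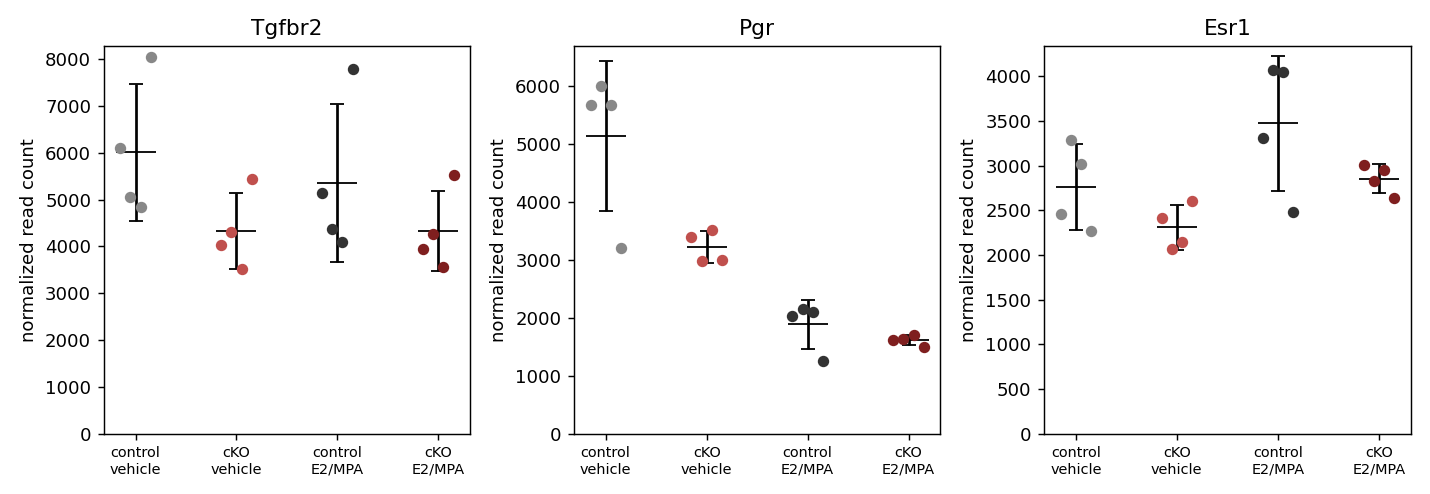
Normalized read counts of Tgfbr2, Pgr and Esr1 (vertical axes, from 0) in each library (points) of the 4 groups, with the group mean and SD (bars). Pgr lies lower in each E2/MPA group than in the vehicle group of the same genotype, and Tgfbr2 levels of control and cKO libraries overlap.

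The first comparison asked how control organoids, with the receptor gene intact, respond to E2/MPA. The hormones raised 890 genes and lowered 579. Abcb5 (ENSMUSG00000072791), which encodes an ABC transporter, had no read in any vehicle library and reached 1551 ± 1137 (adjusted p = 3.8e-07). This mean was 2266-fold above a floor of 3 reads over the vehicle group, and the lowest control E2/MPA library was at 368. Pgr (ENSMUSG00000031870), the progesterone receptor gene, fell by 1.44 on the log2 scale (SE 0.19, adjusted p = 3.8e-04), from 5134 ± 1296 to 1885 ± 424. The calcium-binding protein gene Calb1 rose from 7.86 ± 10.1 to 1219 ± 1175 (adjusted p = 0.00666), Ly6f from 21 ± 15.6 to 1401 ± 672 (adjusted p = 2.6e-05) and the kallikrein gene Klk1b21 from 19.8 ± 26.7 to 2743 ± 2626 (adjusted p = 0.00686). Tcf15, a transcription factor gene, had 2 reads in the vehicle group and reached 177 ± 97.1, Klk1b27 had 1 read and reached 223 ± 212, and Ms4a8a had 4 reads and reached 839 ± 726. Klk1b21 and Klk1b27 belong to a family of near-identical genes, so their separate values are uncertain. Postn, a gene of the matrix protein periostin and a stromal marker, rose from 14.7 ± 25.5 to 627 ± 617 (adjusted p = 0.0170) and was highest in M9 (895) and M12 (1372), the E2/MPA control libraries with the highest stromal marker levels. It was also higher in M10 (110) and M11 (131) than in any control vehicle library (at most 52.8, in M4). Nptx1 (98.8 ± 122 to 3507 ± 3015) and Cuzd1 (384 ± 416 to 12291 ± 9855) also rose. Among the largest falls, the chemokine receptor gene Cxcr4 fell by 3.42 (adjusted p = 0.00194), the tachykinin receptor gene Tacr1 fell by 3.12 (adjusted p = 4.7e-04), Palmd fell by 2.87 and Auts2 fell by 2.80. Tgfbi, named for its induction by TGF-beta, fell by 2.70, from 338 ± 150 to 55.8 ± 39.4 (adjusted p = 0.00314), and the axon guidance receptor gene Robo1 fell by 2.60. Kcng1, a potassium channel gene, fell by 3.96, the oxytocin receptor gene Oxtr fell by 3.49, Cd200r3 fell by 2.99 and Clic6 fell by 2.80. Esr1 (ENSMUSG00000019768), which encodes estrogen receptor alpha, was at 2759 ± 477 and 3476 ± 754 (log2 fold change 0.32, SE 0.15, adjusted p = 0.210), and passed without M12 (adjusted p = 0.0255, over all alternatives 0.0148 to 0.465). With libraries 8 numbers apart as a random block, a setting chosen after seeing the data, Esr1 passed (adjusted p = 0.0259) and 4479 genes were called. Leaving out 1 library ended the calls of Nptx1 (M1, M4, M10 or M11, adjusted p up to 0.0747), Cuzd1 (M1, M10 or M11, up to 0.0722), Kcng1 (M1, M4, M9, M10 or M11, up to 0.0696), Oxtr (M1, M10 or M11, up to 0.0621) and Clic6 (M1 or M11, up to 0.0562). The total of 1469 became 803 without M1, 759 without M10, 781 without M11 and 2230 without M12. Quantile normalization moved the share of calls that were higher from 60.6% to 48.5%.

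Targets of the glucocorticoid receptor, which shares DNA sites with the progesterone receptor, rose as a set in control organoids. Of 17 members 10 rose and 0 fell, with 11 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.5e-08, and adjusted p = 0.00568 with an estimated correlation). The transcription factor gene Zbtb16 went from 1 read in the vehicle group to 66.8 ± 0.658, Sult1a1 rose 8.72-fold, Fkbp5 (ENSMUSG00000024222), which encodes a co-chaperone of steroid receptors, rose 8.39-fold from 160 ± 91.7 to 1233 ± 267, and the metallothionein gene Mt1 rose 4.08-fold. Of 18 cholesterol biosynthesis genes 4 rose and 0 fell, with 9 higher adjusted over the list alone (adjusted p = 9.9e-07, but adjusted p = 0.717 with an estimated correlation). Lss, which encodes lanosterol synthase, rose 1.72-fold from 939 ± 58.5 to 1624 ± 161 (adjusted p = 0.00166). The list was highest in the stroma-rich M12 (mean log2 level 11.13, against 10.71 to 10.78 in the other control E2/MPA libraries). Of 25 TGF-beta/SMAD target genes 1 rose and 7 fell, with 1 higher and 8 lower adjusted over the list alone (adjusted p = 0.00173 for a fall of the set, but adjusted p = 0.808 with an estimated correlation). Tgif1 fell by 0.62 and Cdkn2b fell by 0.58, while Bambi, which encodes a TGF-beta pseudoreceptor, rose 4.02-fold. The list was highest in the stroma-rich M4 (mean log2 level 11.10, against 9.93 to 10.43 in the rest of its group) and M12 (10.73, against 9.54 to 10.27). Of 18 interferon-stimulated genes 0 rose and 1, Mx1, fell, by the same count adjusted over the list alone (adjusted p = 0.0162 for a fall of the set, but adjusted p = 0.808 with an estimated correlation). Mx1 fell by 1.12, while Bst2 and Stat2 had log2 fold changes of 0.18 and -0.02 (adjusted p = 0.683 and 0.951). The other lists did not pass. Of 20 estrogen-responsive genes 3 rose and 1 fell, with 4 and 1 adjusted over the list alone (adjusted p = 0.358). Greb1 rose 2.35-fold and Wnt4 2.05-fold, and the member that fell was Pgr. Of 16 progesterone-responsive genes 4 rose and 2 fell, with 6 and 5 adjusted over the list alone (adjusted p = 0.586). The lipoxygenase gene Alox15 rose 6.35-fold, the hedgehog ligand gene Ihh rose 3.02-fold from 43.5 ± 8.17 to 138 ± 46.9, and the inhibin subunit gene Inhbb fell by 1.12.

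The second comparison asked the same of cKO organoids. E2/MPA raised 447 genes and lowered 245. Abcb5 again had no read under vehicle and reached 443 ± 283 (adjusted p = 4.3e-06). This mean was 614-fold above a floor of 3 reads, and the lowest cKO E2/MPA library was at 131. Ly6f rose 46.3-fold, from 16.8 ± 7.87 to 798 ± 282 (adjusted p = 1.3e-04). Pgr fell by 0.99 (SE 0.19, adjusted p = 0.0085), from 3217 ± 277 to 1611 ± 83.6. Unc93a2 rose from 1.27 ± 1.62 to 108 ± 60.6, Arl4d from 3.51 ± 2.18 to 211 ± 139 and Ms4a8a from 3 reads in the vehicle group to 201 ± 151. Serpina3n, a serine protease inhibitor gene, rose from 0.839 ± 1.19 to 151 ± 243, a mean set by M16 (514, against at most 48.4 in the other libraries of its group). Klk1b21 rose from 1.40 ± 1.68 to 587 ± 568, Calb1 from 0.983 ± 0.705 to 211 ± 229, Nptx1 70.2-fold and Cuzd1 56.7-fold. Tacr1 fell by 2.67 (adjusted p = 0.00264), Auts2 fell by 2.41 and Lrrc9 fell by 1.93. Kcng1 fell by 4.14, Cd200r3 fell by 2.97, Clic6 fell by 2.91, Cxcr4 fell by 2.32, the fibronectin gene Fn1 fell by 2.16, Tecta fell by 1.98 and the Wnt antagonist gene Dkk2 fell by 1.91. Tgfbr2 did not pass in cKO (adjusted p = 0.999) or in control (adjusted p = 0.651), nor did Esr1 in cKO (log2 fold change 0.31, SE 0.15, adjusted p = 0.285). With the random block Esr1 passed in cKO (adjusted p = 0.0394, over all alternatives 0.00258 to 0.463) and 3098 genes were called. Leaving out 1 library ended the calls of Klk1b21 and Cd200r3 (M5, M8, M13, M14 or M15, adjusted p up to 0.0674 and 0.0819), of Kcng1, Clic6 and Cxcr4 (M5, M7, M8, M13, M14 or M15, up to 0.0880, 0.0662 and 0.109), and of Tecta (M5, M7, M13, M14 or M16, up to 0.0767). They also ended for Nptx1 and Calb1 (M5 to M11 or M13 to M15, up to 0.126 and 0.148), for Cuzd1 (these or M1, up to 0.126), for Fn1 (M1, M5, M7, M8, M9, M13, M14 or M15, up to 0.126) and for Dkk2 (M1, M3, M5 to M8 or M13 to M15, up to 0.126). The total of 692 became 400 without M5, 386 without M7, 454 without M8, 362 without M13, 368 without M14 and 419 without M15. DESeq2 called 1255 genes, and upper-quartile rescaling moved the share of calls that were higher from 64.6% to 53.8%.

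Glucocorticoid receptor targets also rose as a set in cKO organoids. Of 17 members 10 rose and 0 fell, with 11 higher adjusted over the list alone (camera adjusted p = 1.7e-10, and adjusted p = 0.00229 with an estimated correlation). Fkbp5 rose 7.92-fold, from 117 ± 47.8 to 887 ± 97.3, Tsc22d3 rose 7.19-fold and Sult1a1 went from 4.29 ± 2.45 to 68.6 ± 31.6. Zbtb16 went from no read to 35.8 ± 18 (lowest library 19.4), a mean 49.6-fold above a floor of 3 reads. Of 18 cholesterol biosynthesis genes 2 rose, with 6 adjusted over the list alone (adjusted p = 4.9e-07, but adjusted p = 0.603 with an estimated correlation). Among them Lss rose 1.49-fold and lost its call without M7, M13 or M14 (adjusted p up to 0.0649). Of 18 interferon-stimulated genes 1 fell, Mx1, by 0.94, from 812 ± 62.3 to 422 ± 12.1, with 4 lower adjusted over the list alone (adjusted p = 4.4e-04, but adjusted p = 0.814 with an estimated correlation). Of 20 estrogen-responsive genes 3 rose and 1 fell, with 4 and 1 adjusted over the list alone (adjusted p = 0.0362, but adjusted p = 0.238 with an estimated correlation). The iron-binding protein gene Lcn2 rose 3.54-fold and Greb1 2.09-fold. The list was highest in the stroma-rich M16 (mean log2 level 10.72, against 10.24 to 10.32 in the other cKO E2/MPA libraries). Of 25 TGF-beta/SMAD target genes 3 fell, with 4 adjusted over the list alone (adjusted p = 0.0403, but adjusted p = 0.814 with an estimated correlation), among them Cdkn2b, which fell by 0.61. In this list the stroma-rich libraries M8 and M16 lay above the rest of their groups, with mean log2 levels of 10.67 and 10.60 against at most 10.02 and 9.81. Cell cycle genes (1 of 30 rose, Rrm2, 2.35-fold, and 1 adjusted over the list alone, with M8 lowest of the vehicle libraries at a mean log2 level of 7.56 against 7.86 to 8.35) and unfolded protein response genes (0 of 15 by either adjustment) were higher as sets, each at adjusted p = 0.0403, and mitochondrially encoded genes (0 of 12 by either adjustment) at adjusted p = 0.0231. For these 3 lists the adjusted p = 0.814 with an estimated correlation. The progesterone-responsive list did not pass (3 of 16 rose and 2 fell, 5 and 2 adjusted over the list alone, adjusted p = 0.630), and its member Ptch1, the hedgehog receptor gene, fell by 0.32.

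The interaction asked whether the hormone response differs by genotype. In both genotypes the same treatment lowered Pgr and raised Abcb5, Ly6f and Fkbp5, and no gene's response was called different. A total of 381 genes rose in both and 194 fell in both, against 24.1 and 8.59 for independent lists, and 0 were called in opposite directions. Across the 16509 genes, which are not independent replicates, the log2 fold changes of the responses had a Pearson correlation of 0.827 and a Spearman correlation of 0.675. limma, edgeR and DESeq2 each called 0 genes for the interaction, with 309 in limma at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. With libraries 8 numbers apart as a random block, a setting chosen after seeing the data, limma also called 0, with 1056 at an unadjusted p under 0.05. The 309 lie below a share of 0.05 of the 16509 genes and the 1056 above it, so the main test may be too strict here. A count of 0 thus does not show that the responses are alike. For Pgr the interaction was 0.44 (SE 0.27, adjusted p = 1.00), for Tgfbr2 0.18 (SE 0.30, adjusted p = 1.00) and for Esr1 -0.01 (SE 0.21, adjusted p = 1.00). The value for Pgr is a smaller fall in cKO. These SEs treat libraries 8 numbers apart as independent, although such libraries deviated together. There were 894 genes called in control alone, and 0 of them passed the interaction test. Over the genes called in control, the median absolute log2 fold change was 0.727 in control and 0.525 in cKO. Over the genes called in cKO it was 0.874 in control and 0.843 in cKO. Choosing genes by their call in 1 genotype favours that genotype. As sets, cell cycle genes (0 of 30 called by either adjustment, including over the list alone, median interaction 0.39, adjusted p = 1.1e-07) and extracellular matrix and protease genes (0 of 20, median 0.24, adjusted p = 0.0348) were higher, and both had an adjusted p = 0.962 with an estimated correlation. The interaction of the cell cycle gene Top2a was 0.58 and that of Mcm2 0.24, and for the laminin gene Lamb3 it was 0.10, all at adjusted p = 1.00. Mean log2 levels of both lists differed between the stroma-rich libraries and the rest of their groups. The cell cycle list was at 8.58 in M4 (8.26 to 8.31 in the rest of its group), 7.56 in M8 (7.86 to 8.35) and 9.06 in M12 (7.86 to 8.25), while M16 (8.28) lay within its group (8.02 to 8.47). The matrix list was at 11.01 in M4 (8.95 to 9.87), 10.19 in M8 (8.71 to 8.93), 10.65 in M12 (8.87 to 9.80) and 10.32 in M16 (8.78 to 9.29). With M4, M8, M12 and M16 left out, camera at the preset correlation still called 2 lists for the interaction, and with the stromal mean as a covariate 3. Both settings were chosen after seeing the data. The stroma-rich libraries are thus not shown to be the source of these set results. Without all libraries with a stromal mean above 7, a setting chosen after seeing the data, limma called 28 genes for the interaction, 5 higher and 23 lower.

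**Figure D2:**
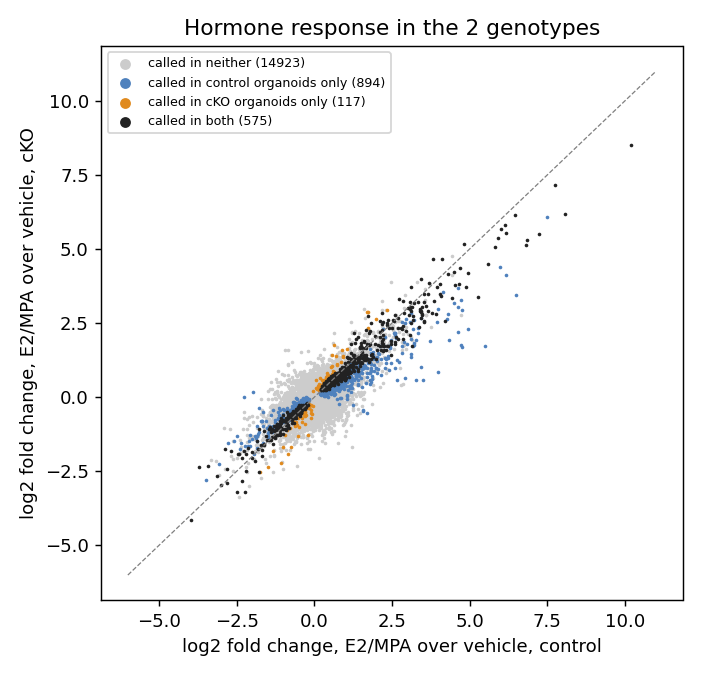
Log2 fold change of E2/MPA over vehicle in control organoids (horizontal axis) and in cKO organoids (vertical axis), 1 point per gene, coloured by the genotype in which the gene passed an adjusted p of 0.05, with a dashed line at equal changes. The 381 genes that rose in both and the 194 that fell in both lie on the same side of 0 on both axes, and 0 genes were called in opposite directions.

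Under vehicle, cKO organoids were compared with control organoids to ask how the genotypes differ without hormone. The labels give PR-Cre for the cKO mice alone. A difference, that of Pgr included, thus cannot be assigned to the deletion apart from Cre. Pgr was at 3217 ± 277 in cKO and 5134 ± 1296 in control (log2 fold change -0.64, SE 0.19, adjusted p = 0.779), with M4 (3205) apart from the other control libraries (5663 to 6002). Esr1 was at 2308 ± 248 and 2759 ± 477 (log2 fold change -0.25, SE 0.15, adjusted p = 0.861). limma called 0 genes, with 984 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0628, while edgeR called 0 and DESeq2 14. limma called 2 genes without M1 and 1 without M2, and, in settings chosen after seeing the data, 8 with the stromal mean as a covariate, 14 without M4, M8, M12 and M16 and 593 without all libraries with a stromal mean above 7. The libraries of the genotypes did not overlap for 497 genes (3.01%, where chance gives 2.86%). Of 25 TGF-beta/SMAD target genes 0 passed by either adjustment, including over the list alone (median -0.10, adjusted p = 0.901). Its member Fn1 had a log2 fold change of -0.57 (adjusted p = 0.933). As a set, cell cycle genes were lower in cKO (0 of 30 called by either adjustment, median -0.41, adjusted p = 9.4e-10, but adjusted p = 0.753 with an estimated correlation). Top2a, a topoisomerase gene of dividing cells, was at 744 ± 191 in cKO and 1079 ± 141 in control (adjusted p = 0.833), and the list was highest in M4 (mean log2 level 8.58, against 8.26 to 8.31 in the other control libraries) and lowest in M8 (7.56, against 7.86 to 8.35 in the other cKO libraries), the stroma-rich libraries of these groups. Immune cell markers (0 of 11, median -1.38) and matrix and protease genes (0 of 20, median -0.57) were lower, both at adjusted p = 0.0141, with an adjusted p = 0.753 and an adjusted p = 0.862 with an estimated correlation. The macrophage gene Lyz2 was at 12161 in M4 and at most 655 in the other vehicle libraries, and M4 also held the highest stromal marker level under vehicle. Mitochondrially encoded genes were lower (0 of 12, median -0.17, adjusted p = 0.00362, but adjusted p = 0.862 with an estimated correlation). Pan-epithelial genes (0 of 15, median 0.09) and p53 targets (0 of 12, median 0.12), both at adjusted p = 0.0143, and immediate early and heat shock genes (0 of 12, median 0.13, adjusted p = 0.0205) were higher, and each had an adjusted p = 0.753 with an estimated correlation. The pan-epithelial list was highest in the stroma-rich libraries of both genotypes, M8 (mean log2 level 13.10, against 12.93 to 12.95 in the rest of its group) and M4 (13.08, against 12.73 to 12.89). The immediate early list was lowest in M7 (9.86, against 10.05 to 10.06).

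Under E2/MPA, the same comparison found 1 gene past the threshold. Lypd5 (ENSMUSG00000030484), a gene of the Ly6/PLAUR domain family, was 8.58-fold higher in cKO, at 72.4 ± 20.8 against 7.79 ± 3.66 (log2 fold change 3.10, SE 0.37, adjusted p = 0.00863), with all 4 cKO libraries above all 4 control libraries. Under vehicle Lypd5 did not pass, but its cKO libraries (25.9 to 63.0) also lay above its control libraries (4.52 to 9.78). The call of Lypd5 under E2/MPA was lost without M9, M11, M13, M14 or M15 (adjusted p up to 0.0673), which left 0 genes, and the count was 2 without M2, 3 without M1 and 10 without M12. edgeR called 1 gene and DESeq2 185, and 1794 genes had an unadjusted p under 0.05 in limma. In settings chosen after seeing the data, limma called 599 with the stromal mean as a covariate, 9 without M4, M8, M12 and M16 and 1394 without all libraries with a stromal mean above 7. The libraries of the genotypes did not overlap for 1019 genes (6.17%, where chance gives 2.86%). Pgr was at 1611 ± 83.6 in cKO and 1885 ± 424 in control (log2 fold change -0.19, SE 0.19, adjusted p = 0.779), and Esr1 at 2855 ± 166 and 3476 ± 754 (-0.26, SE 0.15, adjusted p = 0.569). Of 25 TGF-beta/SMAD target genes 0 passed by either adjustment (median 0.10, mean -0.10, adjusted p = 0.317). Pan-epithelial genes were higher as a set in cKO (0 of 15 by either adjustment, median 0.23, adjusted p = 3.7e-04, but adjusted p = 0.488 with an estimated correlation), with the keratin genes Krt7 and Krt8 at log2 fold changes of 0.25 and 0.19 (adjusted p = 0.682 and 0.762). The list was highest in the stroma-rich M16 (mean log2 level 13.14, against 12.88 to 13.01 in the rest of its group) and M12 (12.99, against 12.72 to 12.81). Immediate early and heat shock genes were higher (0 of 12, and 4 higher adjusted over the list alone, adjusted p = 0.00497, but adjusted p = 0.452 with an estimated correlation), with Ier3 and Fos at 0.21 and 0.55 (adjusted p = 0.311 and 0.604). p53 targets were higher (0 of 12 by either adjustment, adjusted p = 0.0483, but adjusted p = 0.795 with an estimated correlation). Mitochondrially encoded genes were lower (0 of 12 by either adjustment, adjusted p = 0.0272, but adjusted p = 0.965 with an estimated correlation).

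Markers of other cell types differed between libraries within groups. The mean log2 level of 18 stromal and mesenchymal markers was 9.64 in M4, 8.68 in M8, 9.76 in M12 and 9.24 in M16, 7.63 in M1 and 8.27 in M9, and between 4.79 and 6.13 in the others. Col1a1, a fibroblast collagen gene, was at 23062 in M4, 7022 in M8, 14510 in M12 and 10805 in M16. With M4, M8, M12 and M16 left out, a choice made after seeing these levels, E2/MPA changed 2210 genes in control and 959 in cKO organoids, genotype changed 14 under vehicle and 9 under E2/MPA, and limma's interaction count was 0 with 567 at an unadjusted p under 0.05 (DESeq2 and edgeR were not run in this setting). Without all libraries with a stromal mean above 7, which leaves 2 libraries in each control group and 3 in each cKO group, the counts were 2262, 2288, 593, 1394 and 28. With the stromal mean as a covariate they were 3884, 2674, 8, 599 and 0, the last with 634 at an unadjusted p under 0.05.

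**Figure D3:**
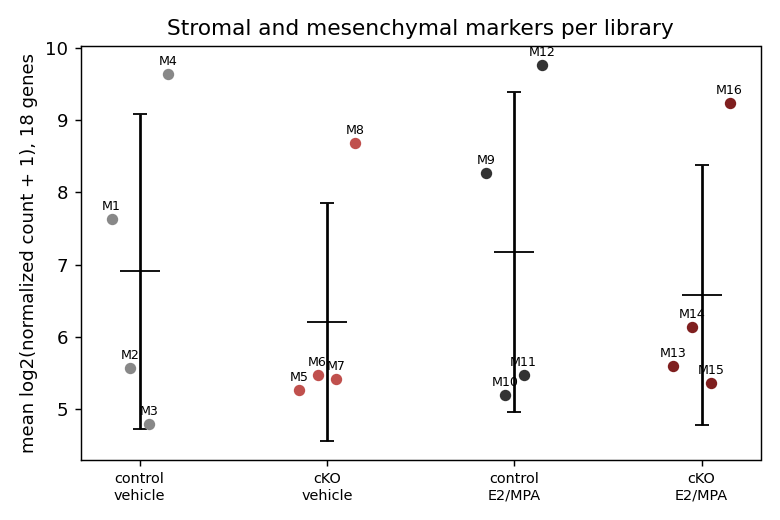
Mean log2(normalized count + 1) of 18 stromal and mesenchymal marker genes (vertical axis) in each library (labelled points) of the 4 groups, with the group mean and SD (bars). M4, M8, M12 and M16 lie between 8.68 and 9.76, each above the other libraries of its group.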

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

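The tests of the stromal marker pattern were chosen after the result was seen, and those on other splits of the samples were fixed before. In 252 groups of 4 values (63 measures), a library stood apart from the other 3 of its group in 33, where chance gives 12.6 by Dixon's test of the gap to the nearest library over the group's range.

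Among mean log2 levels of gene lists, M8 was above the other cKO vehicle libraries for stromal and mesenchymal markers (8.68, others 5.26 to 5.48), smooth muscle markers (5.85, others 3.37 to 3.67), extracellular matrix and protease genes (10.19, others 8.71 to 8.93), TGF-beta/SMAD target genes (10.67, others 9.90 to 10.02) and pan-epithelial genes (13.10, others 12.93 to 12.95). M16 was above the other cKO E2/MPA libraries for TGF-beta/SMAD target genes (10.60, others 9.71 to 9.81) and estrogen-responsive genes (10.72, others 10.24 to 10.32), and M14 for progesterone-responsive genes (9.25, others 8.61 to 8.66). In other groups, M4 was apart for cell cycle genes (8.58, others 8.26 to 8.31), M12 for cholesterol biosynthesis genes (11.13, others 10.71 to 10.78), M7 for immediate early and heat shock genes (9.86, others 10.05 to 10.06) and M6 for histone genes (6.29, others 5.67 to 5.73). The 10 largest genes of M12 took 6.98% of its reads (others 8.06% to 8.18%).

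Among single genes, Postn was high in M4 (52.8, others at most 4.89), M8 (16.7, others at most 1.13) and M16 (566, others at most 50.2). Kcng1 was high in M8 (415, others at most 66.2) and M12 (39.6, others at most 5.72), and Oxtr in M8 (439, others at most 135) and M16 (77.4, others at most 16.7). Dkk2 was high in M8 (617, others at most 264), Cd200r3 in M4 (199.9, others at most 58.7) and Serpina3n in M16 (514, others at most 48.4). Pgr was low in M4 (3205, others at least 5663) and M12 (1252, others at least 2032), Ly6f in M16 (377, others at least 911) and Palmd in M6 (314, others at least 444). Tcf15 was high in M14 (119, others at most 36.9), Tecta in M15 (62.7, others at most 29.7), Lrrc9 in M9 (9.16, others at most 6.05) and Arl4d in M7 (6.78, others at most 2.52). Klk1b27 had its only vehicle reads in M2 (1.13) and M5 (1.12). The interaction passed camera at the preset correlation for the cell cycle list (adjusted p = 1.1e-07) and the extracellular matrix and protease list (adjusted p = 0.0348). Both had an adjusted p = 0.962 with an estimated correlation, and fry called 0 lists. No single gene's response was called different, so a difference by genotype is not shown for either list.

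Other splits of the libraries were counted in fits of the 8 libraries compared. For E2/MPA in cKO, 1 of 35 splits, the real one itself, gave as many genes (878, highest other 2). That share of 2.86% is the smallest that 35 splits can give. The splits also take no account of libraries that deviate together, so chance is argued against but not excluded. For E2/MPA in control, 2 of 35 did (real 484, highest other 729), so that chance cannot be excluded in that fit. The split with 729 set M1, M4, M9 and M12, the control libraries with the highest stromal marker levels, against the rest, and so kept M1 with M9 and M4 with M12. With libraries 8 numbers apart as a random block, a setting chosen after seeing the data, the fit of all 16 libraries gave 4479 genes for this comparison, against 1469 without it. A count of 0 is reached by any split, so the counts of splits say nothing about chance for genotype under vehicle (35 of 35, highest other 1), for genotype under E2/MPA in the 8 libraries (35 of 35, highest other 2) or for the interaction (100 of 100 relabellings). limma had 984, 1794 and 309 genes at an unadjusted p under 0.05 for these in all 16 libraries, edgeR called 0, 1 and 0 and DESeq2 14, 185 and 0. The highest relabelling of the interaction called 960, which points to a structure of the samples.

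The mean of the 18 stromal and mesenchymal markers was high in M4, M8, M12 and M16, 1 library in each group, and 17 of the 18 were highest there in every group, the exception being Fn1 (23256 in M8 and 23332 in M7). Of 12 abundant fibroblast transcripts outside that list, 12 were highest in those libraries in every group, so carried-over stromal cells may be the source. A mesenchymal change of the epithelial cells stays open and cannot be told apart here. The median pan-epithelial gene was 0.18 higher on the log2 scale in those libraries (SD over the groups 0.05). A mesenchymal change would lower it, but so would admixed stromal cells, so this value cannot decide between them. The uterine mesenchyme genes Hand2 (14.2 to 47.3) and Hoxa11 (12.5 to 75.9) were also highest there in every group. Carried-over stromal cells would raise these genes too. The mean log2 level of immune cell markers was highest of their groups in M4 (7.97) and M12 (8.20), with Lyz2 at 12161 and 15703. In M8 (4.49) and M16 (5.21) it lay within the rest of their groups. These values point to admixed immune cells in M4 and M12, but do not show the source of the stromal markers in any of the stroma-rich libraries. The design names no group that sets these libraries apart, since they fall in all 4 groups.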

How the results depend on the processing

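There were 119 named results (108 of them called). Besides leaving out single libraries, 20 settings were tried in all, some of which apply only to gene lists or to the correlation of the responses. Of the 20, 5 were chosen after seeing the data: leaving out M4, M8, M12 and M16, leaving out all libraries with a stromal mean above 7, the stromal mean as a covariate, a term for M4, M8, M12 and M16, and a random block of libraries 8 numbers apart. Counting each library left out as a setting, direction and side of the threshold were kept in 3530 cases, 356 lost the call, 14 gained it and 14 turned direction, and the cause was not tested except where stated. Calls kept without any 1 library were 40 of 63 in control and 26 of 44 in cKO. Depth limits genes with few reads, whose folds are bounds or levels.

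Genes changed by E2/MPA in control organoids (1469) were 484 with only the 8 libraries compared, 556 at an absolute log2 fold change of at least 1, 2549 with array weights, 2210 without M4, M8, M12 and M16, 2262 without all libraries with a stromal mean above 7, 3884 with the stromal covariate, 2983 with the term and 4479 with the random block. Without 1 library they were 759 (M10) to 2230 (M12). In cKO (692) they were 878 with only the 8 libraries compared, 295 at a log2 fold change of at least 1, 1255 with DESeq2, 1678 with array weights, 2288 without the libraries above 7, 2674 with the covariate, 1781 with the term and 3098 with the block. Without 1 library they were 362 (M13) to 827 (M12). Genes changed by genotype under vehicle (0, with 984 at an unadjusted p under 0.05 in limma and 0 in edgeR) were 2 at a mean of at least 50, 14 with DESeq2, 5 with array weights, 14 without M4, M8, M12 and M16, 593 without the libraries above 7, 8 with the covariate, 17 with the term, 1 with the block, and 0 to 2 (M1) without 1 library. Under E2/MPA (1) they were 0 at a mean of at least 50, 185 with DESeq2, 0 with only the 8 libraries compared, 597 with array weights, 9 without M4, M8, M12 and M16, 1394 without the libraries above 7, 599 with the covariate, 74 with the term, and 0 (M9, M11, M13, M14 or M15) to 10 (M12) without 1 library. The interaction (0) gave 28 without the libraries above 7 and 0 without any 1 library.

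The log2 fold change of Tgfbr2 under E2/MPA in cKO (-0.00) was 0.0103 with array weights and -0.13 (M16) to 0.12 (M8) without 1 library. The interaction of Esr1 (-0.01) was 0.0258 without M4, M8, M12 and M16, 0.0458 without the libraries above 7 and -0.16 (M12) to 0.0799 (M4) without 1 library. Without 1 library the genotype effect on Tgfbr2 was -0.58 (M8) to -0.31 (M4) under vehicle and -0.40 (M16) to -0.08 (M12) under E2/MPA. The correlation of the hormone responses was 0.950 over genes called in either, and 0.745 (M8) to 0.825 (M7) without 1 library.

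With an estimated correlation, lists called were 1 for E2/MPA in control (of 4), 1 in cKO (of 8), 0 for genotype under vehicle (of 7), 0 under E2/MPA (of 4) and 0 for the interaction (of 2). With fry they were 3 for E2/MPA in cKO, 0 for genotype under vehicle, 0 under E2/MPA and 0 for the interaction. With quantile normalization they were 4 for genotype under vehicle, 2 under E2/MPA and 1 for the interaction. Without M4, M8, M12 and M16 they were 5 for E2/MPA in cKO, 9 for genotype under vehicle, 4 under E2/MPA and 2 for the interaction. With the stromal mean as a covariate they were 7 for genotype under vehicle, 4 under E2/MPA and 3 for the interaction.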

Other observations

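The tests of stromal reads, of deleted exons, of 1 mislabelled library as the source of reads, of the label of M8 and of a shared animal were chosen after the results were seen, as were the genes named here for genotype. Several lists did not pass for E2/MPA in either genotype, although single members did. Of 14 basal and squamous genes 1 rose and 2 fell in control and 0 and 1 in cKO, the same adjusted over the list alone (camera adjusted p = 0.615 and 0.630). Of 15 pan-epithelial genes 1 rose in each (2 higher and 1 lower in control and 1 higher in cKO adjusted over the list alone, adjusted p = 0.586 and 0.683). Of 20 matrix and protease genes 1 rose in each and 2 fell in control (1 higher and 5 lower in control and 1 higher in cKO adjusted over the list alone, adjusted p = 0.0954 and 0.683). Lor, which encodes loricrin of cornified epithelium, fell by 1.46 on the log2 scale in control organoids (2160 ± 362 to 783 ± 107, n = 4, limma adjusted p = 6.8e-05) and fell by 1.44 in cKO (adjusted p = 1.3e-04). The protease gene Mmp7 rose 3.40-fold in control (2943 ± 1266 to 9494 ± 3100, adjusted p = 0.00382) and 4.44-fold in cKO (3338 ± 934 to 14416 ± 2062, adjusted p = 0.00172). The retinaldehyde dehydrogenase gene Aldh1a1 rose 8.54-fold and 8.22-fold (adjusted p = 0.00528 and 0.00987), and the tight junction gene Cldn3 rose 1.99-fold and 1.49-fold (adjusted p = 1.7e-04 and 0.0131). Upk3b, a mesothelial marker, rose 4.89-fold in control (adjusted p = 0.00122) and was 2.49-fold higher in cKO without passing (adjusted p = 0.0503), and Krt4 rose 3.49-fold in control (adjusted p = 0.00827) and was 1.75-fold higher in cKO without passing (adjusted p = 0.268). limma's interaction did not pass for either (adjusted p = 1.00).

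Without M4, M8, M12 and M16, genotype changed 14 genes under vehicle. Among them Fst, which encodes the activin antagonist follistatin, fell by 2.67 in cKO (SE 0.24), Cdh2 fell by 1.92, Fgf1 fell by 1.67 and Pgr fell by 0.81 (SE 0.07), while Lypd5 rose by 2.61 and Crct1 by 0.82. Under E2/MPA 9 genes changed, and Fst fell by 2.13, and 5 genes were called under both treatments. In all 16 libraries neither Fst (-2.38 under vehicle, adjusted p = 0.779) nor Pgr passed. Because the labels give PR-Cre for the cKO mice alone, these differences, that of Pgr included, cannot be assigned to the deletion apart from Cre. Over all 16 libraries 36 genes had no overlap between the genotypes, and 6 of them differed at least 2-fold. Chance gives 2.57 genes for 16 independent libraries but up to 2.86% of the 16509 genes if libraries 8 numbers apart share a source, so 36 is not shown to exceed chance. Those 6 were Ifi202b (log2 difference -3.03), Muc16 (-1.36), Col27a1 (-1.03), H60c (-1.78), Tigit (1.04) and Lypd5 (2.73).

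The cKO libraries kept reads of Tgfbr2. Reads of carried-over stromal cells are argued against, since the difference was -0.43 (SE 0.12) without M4, M8, M12 and M16 and a loss held up by stromal reads would lie at or below -1. As the source of the reads, 1 mislabelled library is argued against too: 8 of 8 cKO libraries had at least 50% of the control mean of their treatment (58.5% to 103%), and without M8 the difference under vehicle was -0.58 (SE 0.22). The label of M8 itself stays open, as moving M8 gave 8 genes with no overlap of the genotypes at 2-fold or more, against 6 by the labels, and of 12 genes chosen in the other 15 libraries 7 placed the stroma-rich M8 nearer the control mean and 5 nearer the cKO mean, among them Ifi202b (51.0, controls 157 to 616) and Lypd5 (25.9, controls 4.40 to 13.0). Reads outside the deleted exons stay open, because the level of 71.9% of control under vehicle is a total over the gene.

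Libraries 8 numbers apart (M1 with M9 and so on) deviated from their group means together, although the labels give no pairing. Of all pairings of vehicle with E2/MPA libraries within genotype, 1, that pairing itself, reached their mean correlation over genes of 0.551 (highest other 0.508, p = 0.00174, the smallest the pairings can give). A shared animal or preparation is a candidate source. The share of stromal cells as the whole cause is argued against by a narrow margin: with the stromal mean taken out, 25 of the pairings reached the mean correlation of 0.149 (highest other 0.240), barely under the bound of 5%. It stays open for M2 with M10, M3 with M11, M4 with M12 and M8 with M16, whose correlations were then 0.0686, 0.0598, -0.06 and -0.01, while those of the other pairs were 0.174 to 0.351.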
